A study of Mus musculus with 42 samples.

How the data were processed

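RNA was measured in CD4+ Tconv and Treg sorted by flow cytometry from spleens of NOD mice with a GFP reporter of Foxp3, on Affymetrix ST1.0 gene arrays, which read each transcript cluster through many short probes. The labels gave 22 groups: 2 cell types, 2 settings (KT3 injected, or added to splenocytes in culture) and 5 times, with 2 arrays each, and 1 array per cell type 24 h after rat IgG. Group, time and array number were taken from the labels. The labels give all in vivo mice as females of 8 weeks, and in culture the arrays numbered 1 as female mice of 9 weeks and those numbered 2 as males of 14 weeks, so that sex and age go with the array number there. They also give each in vivo sample as single or double sorted. Whether arrays of 1 group came from separate in vivo animals is not given in the sources used here.

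The values used were intensities that the authors deposited, 1 per transcript cluster and array, on a linear scale from 4.8403 to 29756.3596, with array medians between 87.6 and 116.4. Per the series design text, RNA of sorted cells was amplified, labelled and hybridized, and the raw data were preprocessed with RMA in GenePattern; per the submitters' processing notes, Affymetrix Power Tools and RMA were used. Their versions, and whether all arrays were normalized together, are not given in the sources used here. RMA subtracts a modelled background, so that dim genes keep little of their change. It commonly also forces arrays to like distributions, which would hide a shift of all genes in 1 direction. The deposited arrays did not have like distributions, with interquartile ranges of 1.645 to 3.208 log2 units and upper quartiles of 196.6 to 334.2 in intensity. Differences of scale between arrays thus remained in these values. The design text also states that averaged expression values were used, while the deposited table holds 1 column for each of the 42 arrays, and these were used here.

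The table held 24922 transcript clusters. A gene table for the platform gave 1 symbol for 21425 of them and several for 1399, and did not list 2098. Of the clusters with 1 symbol 21347 were matched to a current gene table by Entrez ID, and 0 symbols were updated. Among 19752 distinct symbols 921 had more than 1 cluster, of which the one with the highest mean was kept. Genes above the array median on at least 2 arrays were tested, which left 12425 and removed 7327 as dim.

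Values were taken to log2 without an offset and fitted with limma (3.58.1, in R 4.3.3) in 1 model of 22 group means over all 42 arrays, with 20 residual and 5.01 prior degrees of freedom. The shared estimate of spread was needed because most groups hold 2 arrays and the IgG groups 1, which was taken to vary like the other groups. Moderated tests of either direction (two-sided) with eBayes gave each contrast: time against 0 h in each cell type and setting, Treg against Tconv at 0 h, the difference between the Treg and Tconv responses, KT3 against IgG, and IgG against 0 h. The in vivo and in vitro responses were compared by limma's moderated F-test over the 4 time differences. P-values were adjusted by Benjamini-Hochberg over the 12425 genes of each contrast, and a gene was called under 0.05. Errors in the text are standard errors from this model. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9. The number of arrays, mostly 2 per group, limits the precision of every value.

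The comparisons, the model, 33 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named Foxp3, Il7r, Id2, Id3 and Gfi1. In each response and IgG contrast it named the 3 called genes with the largest rise and the 3 with the largest fall. Only genes whose groups do not overlap were taken there, and 6 and 6 likewise for each comparison at 0 h. For each response difference 3 and 3 called genes were taken by size alone, without a check for overlap. For each F-test it named the 6 called genes with the largest single difference. Of each list it named up to 4 called members with the largest change, or the largest change where none was called. All members of the sex-linked and other-cell lists were named where levels are given. Symbols starting with Gm and a digit, ending in Rik, or starting with Mir, Snor, Trav, Traj, Trbv, Igh, Igk or Igl were left out. The lists cover responses to stimulation (20), identity of Treg and Tconv (2), regulators known from work on these samples (1), markers of other cell types (9) and sex-linked genes (1), with 359 members in all, of which 31 had no cluster with 1 name, 23 were removed as dim and 305 were tested. Of these lists 31 had enough tested members. They were tested with limma's fry, adjusted over all lists and contrasts of a family. The fry test asks whether a set moves on balance in 1 direction and does not compare it with other genes. It called 58 of 248 tests in vivo, 92 of 248 in vitro, 19 of 62 at 0 h, 4 of 248 for response differences, 5 of 124 with IgG and 19 of 248 for in vivo minus in vitro. With camera and a correlation estimated from the data, 20, 0, 7, 1, 2 and 2 of these held.

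Array numbers are shared between groups in the labels, so the pairing was checked on the deviations of arrays from their group means. In vivo these correlated across genes within a cell type for every pair of times, by 0.65 to 0.78 in Tconv and 0.41 to 0.70 in Treg (10 of 10 pairs above 0.1 in both), so there the number was taken to pair the samples of a cell type. In culture they did so by -0.13 to 0.71 in Tconv (5 of 10 pairs above 0.1) and -0.39 to 0.60 in Treg (7 of 10), and the pairing there rests only on the labels, which tie the number to the sex and age of the mice. A replicate block for each cell type and setting, which leaves 16 residual degrees of freedom, was added after this was seen and is printed beside a result where it changed a call or moved a count by more than 1.5 times.

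Alternatives fixed in advance were a replicate block within each setting, a fit within 1 setting, quantile normalization, median centring, no filter on dim clusters, every cluster tested whether named or not, the number of sorts as a covariate in vivo, camera for the lists, and leaving out each array in turn. Added after the data were seen were the finer replicate block, a fit without the 3 in vitro arrays of narrowest range and, for comparisons that do not use it, a fit without the in vitro Tconv 0 h array number 1, whose group had a residual of 0.521 (root mean square) against a median of 0.182 over groups. The procedure was tested on simulated data with 200 changed genes of 12425. For 4-fold changes and equal spread at 8 h it recovered 97% in Tconv in vivo, 89.4% in Treg in vivo, 77.3% of response differences in vivo, 87.9% in Tconv in vitro and 97% in Treg in vitro, and for the F-tests 83% and 77.5%. For 2-fold changes at 8 h it recovered 46.3%, 59.7%, 10.4%, 49.3% and 58.2% in the same order, so most 2-fold response differences would be missed. With the spread as observed it recovered 65.2% of 4-fold response differences in vivo. With the spread of each group as observed, it called 1283 of 12225 unchanged genes (10.49%) in Tconv in vitro at 8 h, against 0 in Tconv in vivo, so in vitro Tconv counts that include that array are not held to the stated error rate.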

Results

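The series followed the answer of CD4+ T cells to a T cell receptor stimulus in NOD mice, a strain that develops autoimmune diabetes. The mice carried a green fluorescent protein (GFP) reporter of Foxp3, the transcription factor that defines regulatory T cells (Treg), so that Treg and conventional CD4+ T cells (Tconv) of the spleen could be sorted apart. KT3, an antibody against CD3, the signalling part of the T cell receptor complex, was either injected into mice (in vivo) or added at 1.25 µg/ml to cultured splenocytes (in vitro). RNA of Tconv and Treg was measured before (0 h) and 2, 8, 24 and 72 h after KT3, with 2 arrays for each cell type, setting and time. One further array per cell type was made 24 h after injection of rat IgG, so that 42 arrays in 22 groups were used. Differences are given as log2 fold changes ± SE with n = 2 arrays per group unless said otherwise, and a gene was called at an adjusted p under 0.05 over the 12425 genes tested. The small number of arrays limits the precision of each value, and nothing in the labels says that in vivo arrays of 1 group came from separate animals, so p-values measure only the spread between these samples, which may be technical. Foxp3 lay between 11.30 and 12.34 (log2 intensity) on the Treg arrays and between 7.02 and 8.20 on the Tconv arrays, including the in vitro Treg arrays, whose gate the labels give as GFP negative.

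In each of the 10 in vivo groups the array numbered 1 in the labels held more RNA of B cell, macrophage, neutrophil and platelet markers than the array numbered 2. Markers of CD8 T cells were higher in all 10 too, those of erythroid and plasma cells in 9 and those of dendritic and NK cells in 8 and 6. The mean difference over 28 markers ran from 0.76 ± 0.14 (SE over markers) in Tconv at 24 h to 2.05 ± 0.27 in Treg at 72 h. There Lyz2, a lysozyme of macrophages and neutrophils, stood at 10.85 on number 1 and 4.92 on number 2. In vitro, the Tconv 0 h array number 1 stood apart, with a mean correlation of 0.787 with the other arrays, against 0.91 for the next lowest, and an interquartile range of 1.645 log2 units against 2.097 to 3.208 on the others. Its deviation from its group correlated across genes with that of number 1 of Tconv at 8 h (0.71) and of Treg at 0 h (0.65), which had the next narrowest ranges (2.097 and 2.192), and these 2 with each other (0.71). It enters every in vitro Tconv comparison and the shared estimate of spread, so counts without it are given where they differ by more than 1.5 times. Counts without single arrays are in the order 0 h number 1, later number 1, 0 h number 2, later number 2. The lone array left was taken to vary like other groups. In vivo, with no replicate block, these fits mix the number effect with reliance on 1 array. For genes named below, a call lost without 1 array is stated beside them. Both IgG arrays carry number 2.

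**Figure D1:**
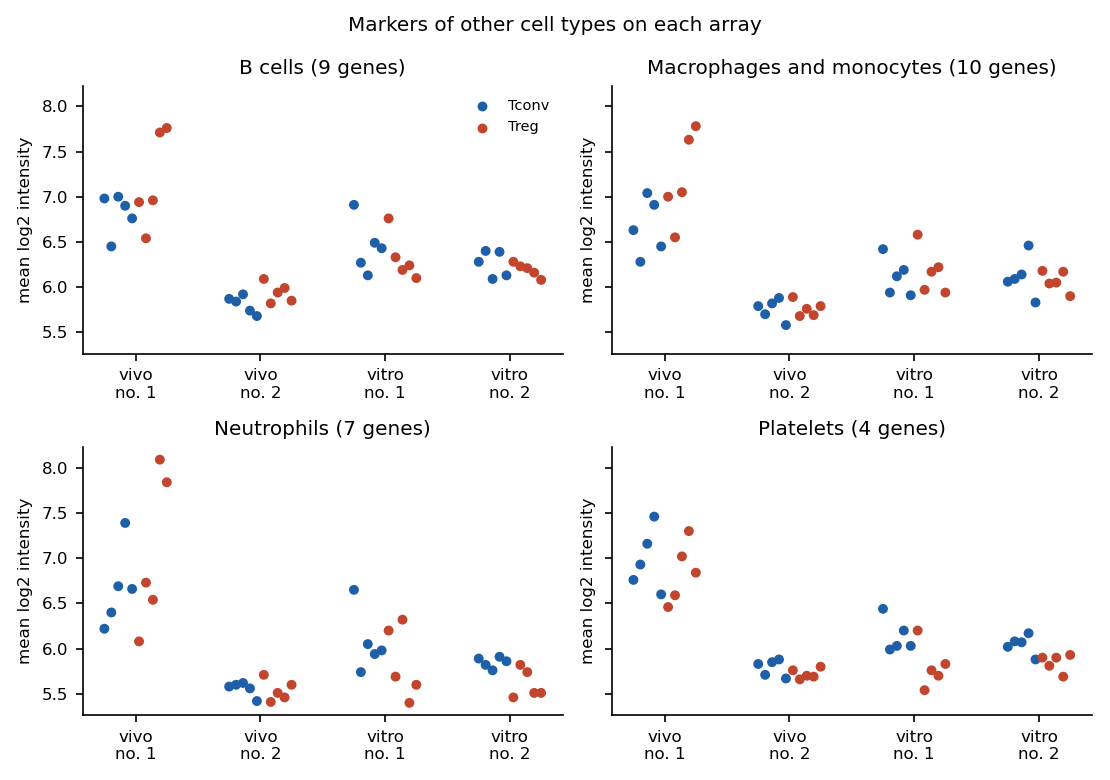
Mean log2 intensity of the markers of B cells (9 genes), macrophages and monocytes (10), neutrophils (7) and platelets (4), with 1 point per array, by setting and array number. In vivo, number 1 arrays lie above number 2 arrays, by 0.76 to 2.05 on average over 28 tested markers.

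Before the stimulus in vivo, Treg expressed more of the genes that mark the lineage. Il2ra, the alpha chain of the interleukin-2 receptor, was 4.83 ± 0.31 (SE, adjusted p = 1.88e-10) higher than in Tconv. The inhibitory receptor Ctla4 was higher by 4.33 ± 0.31, the transcription factor Ikzf2 4.14 ± 0.34 and Foxp3 4.02 ± 0.28. Rgs1, a regulator of G protein signalling, the receptor Klrg1 and the cytotoxic protease gene Gzmb were also higher, by 4.07 ± 0.45, 4.07 ± 0.42 and 3.28 ± 0.34. Tconv expressed more Igfbp4 (-3.61 ± 0.30, Treg minus Tconv), Dapl1 (-3.25 ± 0.55) and the phosphodiesterase Pde3b (-3.15 ± 0.60). The neuropeptide receptor Vipr1 (-2.69 ± 0.35), Sema4a (-2.38 ± 0.32) and Id2, an inhibitor of E protein transcription factors (-2.11 ± 0.34), were lower in Treg as well. Of the Treg signature, 24 of 25 genes were higher in Treg and 1 was not called (24 adjusted over the list alone, list test adjusted p = 3.08e-13). Of the activation receptors 8 of 13 were higher, 5 were not called, and 9 were higher and 1 lower adjusted over the list alone (adjusted p = 5.56e-07). Of the genes known to be higher in Tconv, 5 of 11 were lower in Treg and 6 were not called (8 adjusted over the list alone, adjusted p = 0.00462, adjusted p = 0.104 with an estimated correlation). In all, 385 genes differed (321 were higher and 64 lower in Treg), 630 with a replicate block. Without Tconv number 1, Tconv number 2, Treg number 1 or Treg number 2 the count was 217, 206, 155 or 283. Id3 was higher in Treg by 1.02 ± 0.27 (SE, adjusted p = 0.034), but lost its call without each of these 4 arrays (0.85, 1.19, 1.24 and 0.80) and after quantile normalization (1.02).

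In the culture experiment the same comparison at 0 h gave a like picture for the lineage genes. Il2ra was higher in Treg by 4.99 ± 0.31, Ctla4 by 4.60 ± 0.31, Rgs1 by 4.27 ± 0.45 and Foxp3 by 3.97 ± 0.28. Igfbp4 (-3.12 ± 0.30) and Pdlim4 (-1.74 ± 0.26) were lower. Of the Treg signature 23 of 25 genes were higher (24 adjusted over the list alone, adjusted p = 4.67e-13), and 23 also without the Tconv array number 1. The number of genes called depended on that array: 1396 were called with it (1078 were higher and 318 lower), 197 without it, of which 171 were shared, 301 without the 3 arrays of narrowest range, and 4398 with a replicate block. Leaving out Tconv number 2, Treg number 1 or Treg number 2 gave 7570, 3969 or 133. Of the called genes 77.2% were higher, 53.7% after quantile normalization and 88.7% after median centring, and the median of all genes moved from 0.18 to 0.07 with the first scaling and to 0.32 with the second.

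At 2 h in vivo, Tconv had raised genes that T cell receptor signalling switches on. Irf4, a transcription factor induced in activated lymphocytes, rose by 4.83 ± 0.27 (SE, adjusted p = 7.31e-12), Il2ra by 4.56 ± 0.31, and the orphan nuclear receptors Nr4a3 and Nr4a1 by 4.33 ± 0.42 and 3.89 ± 0.36. The cytokine genes Il2 (2.95 ± 0.27), Lif (2.43 ± 0.37), Il21 (2.25 ± 0.20) and Tnf (2.13 ± 0.30) rose with them. Of the early T cell receptor response genes, 13 of 17 rose and 4 were not called (16 adjusted over the list alone, list test adjusted p = 2.92e-06). Of the NF-kB and NFAT targets, 9 of 10 rose and 1 was not called (9 adjusted over the list alone, list test adjusted p = 4.22e-07). Nfkbid (2.89 ± 0.31) and the NF-kB inhibitor Tnfaip3 (2.41 ± 0.35) led them. Of the cytokines and chemokines, 8 of 17 rose and 9 were not called (13 adjusted over the list alone, list test adjusted p = 5.86e-09). Of the inhibitory receptors, 5 of 8 rose and 3 were not called (7 adjusted over the list alone, list test adjusted p = 8.17e-06). Of the ribosome biogenesis genes, 10 of 14 rose and 4 were not called (14 adjusted over the list alone, list test adjusted p = 5.37e-05), among them Polr1b, a subunit of RNA polymerase I (1.95 ± 0.24). Falls were fewer: Slc16a5, a monocarboxylate transporter, fell by 1.48, a call lost without the 2 h array number 1 (-1.32). In all, 436 genes were called (378 were higher and 58 lower, 293 of them at least 2-fold). The count was 767 with a replicate block, 913 without the in vitro Tconv array that stood apart, and 236, 133, 178 and 463 without each array in turn. On number 1 the mean of macrophage markers went from 6.63 at 0 h to 7.04 at 2 h, that of neutrophil markers from 6.22 to 6.69 and that of platelet markers from 6.76 to 7.16. On number 2 they went from 5.79 to 5.82, 5.58 to 5.62 and 5.83 to 5.85. Of the called genes 86.7% were higher, 65% after quantile normalization and 95.1% after median centring.

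At 8 h in vivo, genes of ribosome production and metabolism were among those raised in Tconv. Il21, a cytokine of helper T cells, rose by 4.90 ± 0.20 (SE, adjusted p = 5.13e-15), the inhibitory receptor Lag3 by 4.08 ± 0.33, Il2ra by 3.98 ± 0.31 and the costimulatory receptor Tnfrsf9 by 3.52 ± 0.27. Of the ribosome biogenesis genes, 14 of 14 rose (14 adjusted over the list alone, list test adjusted p = 6.25e-06, adjusted p = 0.096 with an estimated correlation). Of the glycolysis genes, 8 of 10 rose and 2 were not called (8 up and 1 down adjusted over the list alone, list test adjusted p = 0.000232, adjusted p = 0.274 with an estimated correlation), 1 falling with a replicate block, with the enzyme Tpi1 at 2.67 ± 0.41. Of the cholesterol synthesis genes, 7 of 9 rose and 2 were not called (9 adjusted over the list alone, list test adjusted p = 0.000751, adjusted p = 0.274 with an estimated correlation). Of the ATF4 and amino acid response genes, 8 of 12 rose, 1 fell and 3 were not called (8 up and 1 down adjusted over the list alone, list test adjusted p = 0.000486, adjusted p = 0.294 with an estimated correlation), with the mitochondrial serine enzyme Shmt2 at 2.65 ± 0.30. Of the heat shock genes, 5 of 7 rose and 2 were not called (5 adjusted over the list alone, list test adjusted p = 9.9e-05, adjusted p = 0.222 with an estimated correlation), with the chaperone Hspd1 at 2.80 ± 0.38. The largest falls were those of Il7r, the receptor of the survival cytokine interleukin-7 (-4.07 ± 0.52 SE, adjusted p = 4.53e-06), and the receptor adaptor Trat1 (-3.50 ± 0.68). Selenop (-3.38 ± 0.45), Dapl1 (-3.01 ± 0.55) and S1pr1, which guides T cells out of lymphoid organs (-2.79 ± 0.41), fell too. Of the quiescence and homing genes, 7 of 14 fell and 7 were not called (7 adjusted over the list alone, list test adjusted p = 0.0108, adjusted p = 0.383 with an estimated correlation). Of the genes higher in resting Tconv, 8 of 11 fell and 3 were not called (8 adjusted over the list alone, list test adjusted p = 0.00476, adjusted p = 0.294 with an estimated correlation). Among interferon-stimulated genes 1 of 16 rose and 4 fell (1 up and 5 down adjusted over the list alone, 8 down with a replicate block), with a list test adjusted p of 0.102 that became 0.0266 with the block. The CD8 T cell markers went from 7.27 to 7.76 on number 1 and from 6.91 to 7.25 on number 2 (list test adjusted p = 0.254, 0.0266 with the block). In all, 2607 genes were called (1794 were higher and 813 lower, 1494 at least 2-fold), and 1817, 1574, 1511 and 1773 without each array in turn. Of the called genes 68.8% were higher, 54.5% after quantile normalization and 81.6% after median centring, and median centring moved the median of all genes from -0.06 to 0.10.

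At 24 h in vivo the largest rises in Tconv were those of Lag3 (3.96 ± 0.33 SE, adjusted p = 3.89e-08), the histone gene H2ac4 (3.87 ± 0.34) and Tnfsf4, the ligand of the receptor OX40 (3.78 ± 0.30). Of the cell cycle genes, 19 of 21 rose and 2 were not called (21 adjusted over the list alone, list test adjusted p = 3.96e-06), among them topoisomerase Top2a (3.24 ± 0.37) and the mitotic motor Kif11 (3.23 ± 0.33). Of the inhibitory receptors, 4 of 8 rose and 4 were not called (4 adjusted over the list alone, list test adjusted p = 4.63e-05), with Ctla4 at 2.77 ± 0.31. Of the Treg signature, 5 of 25 rose and 20 were not called (7 adjusted over the list alone, list test adjusted p = 0.00752, adjusted p = 0.228 with an estimated correlation), with the interleukin-2 receptor chain Il2rb at 1.95 ± 0.25. Slc16a5 fell by 2.38 ± 0.27. In all, 298 genes were called (282 were higher and 16 lower), 452 with a replicate block and 216, 140, 137 and 260 without each array in turn. At 72 h Myb, a transcription factor of cycling progenitors (2.34 ± 0.30 SE, adjusted p = 0.000181), Itih5 (2.28 ± 0.33), Lag3 (2.26 ± 0.33) and Gzmb (2.24 ± 0.34) were still higher than at 0 h. On number 1 neutrophil markers went from 6.22 at 0 h to 7.39 at 72 h, erythroid markers from 6.39 to 7.34 and platelet markers from 6.76 to 7.46, while on number 2 neutrophil markers went from 5.58 to 5.56. Slc16a5 was lower (-2.60 ± 0.27). The 72 h count was 36 (33 were higher and 3 lower), 64 with a replicate block, 57 without the in vitro array that stood apart, and 22, 15, 10 and 15 without each array in turn.

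**Figure D2:**
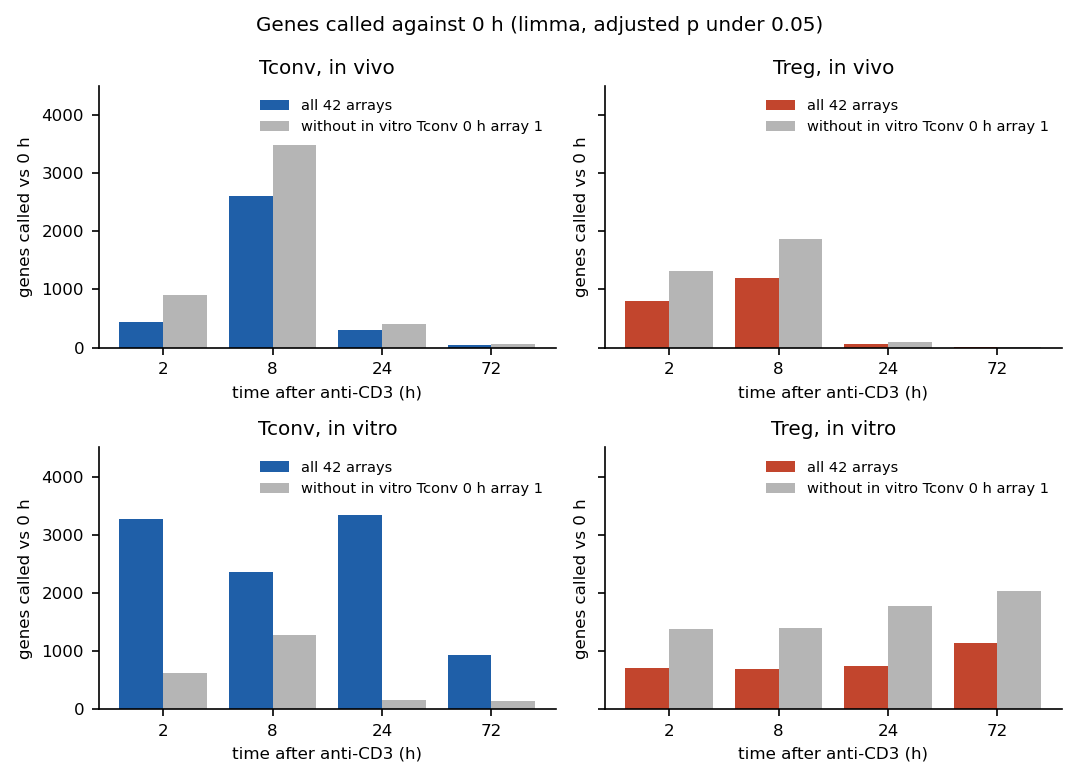
Number of genes called (y axis, adjusted p under 0.05) against 0 h by time after KT3 (x axis), with 1 bar for the fit to all arrays and 1 for the fit without the in vitro Tconv 0 h array number 1, in 4 panels for cell type and setting. In vivo the count in Tconv peaks at 8 h with 2607, while in vitro the Tconv count at 24 h is 3336 with that array and 160 without it.

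In Treg at 2 h in vivo the largest rises were those of Lif, a cytokine of the interleukin-6 family (4.19 ± 0.37 SE, adjusted p = 3.99e-08) and the lipid transporter Mfsd2a (3.56 ± 0.30). Tbx21, the T-bet regulator of type 1 helper cells (3.53 ± 0.33), Nr4a3 (3.50 ± 0.42), Myc (3.14 ± 0.45), Irf4 (3.07 ± 0.27) and the hexokinase Hk2 (2.95 ± 0.34) rose as well. Of the early receptor response genes, 11 of 17 rose and 6 were not called (14 adjusted over the list alone, list test adjusted p = 4.84e-05). Of the activation receptors, 9 of 13 rose and 4 were not called (10 up and 1 down adjusted over the list alone, list test adjusted p = 9.07e-05), 1 falling with a replicate block. Of the STAT5 and SOCS feedback genes, which answer to interleukin-2, 6 of 8 rose and 2 were not called (7 adjusted over the list alone, list test adjusted p = 2.92e-06), with Cish at 2.21 ± 0.23 and Socs1 at 1.71 ± 0.24. Of the ribosome biogenesis genes, 11 of 14 rose and 3 were not called (14 adjusted over the list alone, list test adjusted p = 4.31e-06), with Rrs1 at 2.71 ± 0.23. The cell cycle phosphatase Cdc25b (-1.55 ± 0.27) and the myosin Myo1f (-1.71 ± 0.25) fell. In all, 802 genes were called (626 were higher and 176 lower, 499 at least 2-fold). They were 1319 without the in vitro Tconv array that stood apart and 488, 245, 348 and 628 without each array in turn. On number 1 neutrophil markers went from 6.08 to 6.54, erythroid markers from 6.11 to 6.64 and platelet markers from 6.46 to 7.02, and none of the 3 rose on number 2. Of the called genes 78.1% were higher, 60.3% after quantile normalization and 87.8% after median centring.

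At 8 h in vivo Treg had raised the transglutaminase Tgm2 (3.76 ± 0.40 SE, adjusted p = 1.78e-06) and the chemokine receptor Ccr8 (3.47 ± 0.34). Il12rb2, a chain of the interleukin-12 receptor (3.39 ± 0.49), Tnfrsf9 (2.94 ± 0.27) and Gzmb (2.40 ± 0.34) rose as well. On the arrays numbered 1 the markers of other cells rose too, with the mean of neutrophil markers going from 6.08 at 0 h to 7.84 at 8 h and that of B cell markers from 6.94 to 7.76. On number 2 neither rose (B cell markers 6.09 and 5.85), while CD8 T cell markers went from 6.98 to 7.77 and from 6.66 to 6.80 (list test adjusted p = 0.336, 0.025 with a replicate block). The mean of NK cell markers went from 4.69 to 5.47 and from 4.59 to 4.95. Of these 6 markers only Eomes passed the dim filter, and it is also in the list of helper lineage regulators. Over all arrays Eomes ranged from 5.98 to 9.78, too little to give the rise of the mean on number 1 by itself. Dim NK markers thus rose there too, and Ncr1 had its highest value of all arrays (5.74) on that one. On number 2 the mean cannot tell NK cell RNA from a rise of Eomes in the sorted T cells. Tgm2 rose on both, from 7.16 to 10.83 on number 1 and from 6.53 to 10.39 on number 2. Of the ribosome biogenesis genes, 11 of 14 rose and 3 were not called (14 adjusted over the list alone, list test adjusted p = 1.86e-05). Of the glycolysis genes, 7 of 10 rose, 1 fell and 2 were not called (9 up and 1 down adjusted over the list alone, list test adjusted p = 0.00214, adjusted p = 0.233 with an estimated correlation). Of the heat shock genes, 5 of 7 rose and 2 were not called (5 adjusted over the list alone, list test adjusted p = 0.000283, adjusted p = 0.101 with an estimated correlation). Genes that fell included Lpar6, a receptor of lysophosphatidic acid (-2.27 ± 0.43), the chemokine receptor Ccr2 (-1.83 ± 0.31), the integrin Itgae (-1.94 ± 0.37) and Nrp1 (-1.82 ± 0.30). Of the quiescence and homing genes, 1 of 14 rose, 7 fell and 6 were not called (1 up and 7 down adjusted over the list alone, list test adjusted p = 0.0683), and with a replicate block the list was called (adjusted p = 0.0266). In all, 1201 genes were called (790 were higher and 411 lower, 643 at least 2-fold). They were 1820 with a replicate block, 1869 without the in vitro Tconv array that stood apart and 620, 436, 425 and 683 without each array in turn. Of the called genes 65.8% were higher, 52% after quantile normalization and 75.3% after median centring.

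Later calls in Treg in vivo were few without a replicate block. At 24 h Eomes, a transcription factor of effector T cells, was higher by 2.29 ± 0.30 (SE, adjusted p = 0.000597), the actin-severing protein Scin by 2.15 ± 0.31 and Gzmb by 2.08 ± 0.34. The call of Scin was lost without the 24 h array number 1 (1.66) and that of Gzmb without the 0 h array number 2 (2.16). On number 1 neutrophil markers stood at 6.73, against 6.08 at 0 h, and on number 2 at 5.41, against 5.71. Of the cell cycle genes, 2 of 21 rose and 19 were not called (21 adjusted over the list alone, list test adjusted p = 0.00175), and 13 rose with a replicate block. At 24 h 60 genes were called (56 higher, 4 lower). They were 200 with a replicate block, 101 without the in vitro Tconv array that stood apart and 27, 2, 4 and 144 without each array in turn. At 72 h 3 genes were called, all higher, Gzmb (2.29 ± 0.34 SE, adjusted p = 0.00464), Dlgap5, a protein of the mitotic spindle (1.29 ± 0.24), and Podnl1 (1.06 ± 0.19). On number 1 neutrophil markers stood at 8.09 then, against 6.08 at 0 h. The call of Gzmb was lost without either 0 h array (2.21 and 2.38) or the 72 h array number 1 (2.35) and with the number of sorts as a covariate (2.29). That of Dlgap5 was lost without the same 3 arrays (1.55, 1.03 and 1.02) and that of Podnl1 without each array (0.92 to 1.21). The calls of both were also lost after quantile normalization (1.20 and 1.01), after centring (1.34 and 1.11), and with no filter, in vivo arrays alone or the sort covariate (1.29 and 1.06). The count was 53 with a replicate block and 0, 0, 0 and 20 without each array in turn, and limma gave 276 genes at an unadjusted p under 0.05. Foxp3 was called in none of the Treg comparisons with 0 h in vivo. Its changes were 0.26 ± 0.28, 0.04 ± 0.28, -0.13 ± 0.28 and -0.001 ± 0.275 at 2, 8, 24 and 72 h (adjusted p = 0.813, 0.967, 0.999 and 1).

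Il7r, the E protein inhibitors Id2 and Id3 and the transcriptional repressor Gfi1 were fixed as a list of regulators because they are known from work on these samples, so that the list is not independent evidence of its direction. In Tconv in vivo Gfi1 rose by 1.92 ± 0.21 at 2 h and 1.70 ± 0.21 at 8 h. At 8 h Il7r fell by 4.07 ± 0.52, Id2 fell by 1.02 ± 0.34 and Id3 rose by 0.81 ± 0.27 (adjusted p = 0.0321 and 0.0329). Id3 was still higher at 24 h (1.21 ± 0.27) and 72 h (1.28 ± 0.27). In Treg at 8 h Id2 rose by 1.52 ± 0.34 and Id3 fell by 1.38 ± 0.27, while Il7r (-1.15 ± 0.52, adjusted p = 0.201) and Gfi1 (0.40 ± 0.21) were not called. With a replicate block Il7r was (adjusted p = 0.0357). Of the 4 genes in the list 2 rose and 2 fell in Tconv at 8 h (2 and 2 adjusted over the list alone), with a median of -0.10 and a list test that pointed upward (adjusted p = 0.939). In Treg at 8 h 1 rose and 1 fell (1 and 2 adjusted over the list alone, adjusted p = 0.907), 2 falling with a replicate block. The Tconv calls at 8 h were lost without each of the 4 arrays, for Id2 with values of -1.16 to -0.88 and for Id3 of 0.64 to 0.98. Median centring ended that of Id2 (-0.86) and quantile normalization that of Id3 (0.81). For Id3 the call was also lost at 24 h without either 24 h array (1.33 and 1.10) or 0 h number 1 (1.04). It was lost at 72 h without each array (1.10 to 1.45) and after centring (1.26), and in Treg at 8 h without 0 h number 2 (-1.16).

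**Figure D3:**
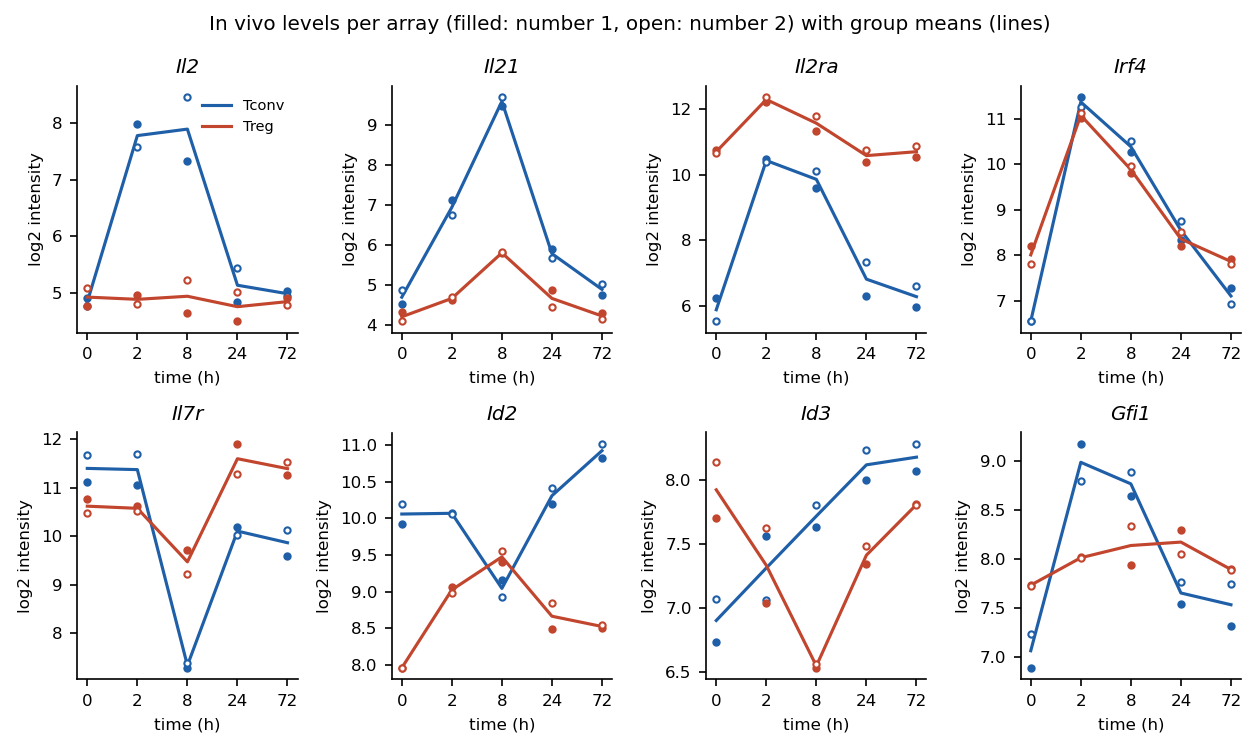
Log2 intensity of Il2, Il21, Il2ra, Irf4, Il7r, Id2, Id3 and Gfi1 by time after KT3 in vivo in Tconv and Treg. Filled points are arrays numbered 1, open points arrays numbered 2 and lines the group means, and at 8 h the Tconv line of Il7r lies 4.07 below its start.

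Whether the response itself differed between the cell types was tested as the Treg change minus the Tconv change. At 2 h in vivo 6 genes differed: Il2 (-2.99 ± 0.38 SE, adjusted p = 0.000363), Il2ra (-2.96 ± 0.43), Il21 (-1.79 ± 0.28) and Gfi1 (-1.64 ± 0.29) had lower changes in Treg. Socs2, a feedback inhibitor of cytokine signalling (1.95 ± 0.35), and the interleukin-23 receptor Il23r (1.87 ± 0.30) had higher ones. Of the cytokines and chemokines 2 of 17 were lower in Treg and 15 were not called (2 up and 7 down adjusted over the list alone, list test adjusted p = 0.00483). At 8 h 29 genes differed (12 were higher and 17 lower in Treg), and among them Il21 (-3.29 ± 0.28 SE, adjusted p = 1.35e-07), Il2ra (-3.11 ± 0.43), Il2 (-3.05 ± 0.38) and Id3 (-2.19 ± 0.38) were lower in the Treg response. Il2ra started 4.83 higher in Treg than in Tconv and was still 1.72 higher at 8 h, while Il2 went from 0.09 to -2.96. Scin (2.55 ± 0.43) and Id2 (2.53 ± 0.48) were higher. Of the cytokines and chemokines 2 of 17 were again lower and 15 were not called (3 adjusted over the list alone, list test adjusted p = 0.0282, adjusted p = 0.132 with an estimated correlation). Il7r (2.92 ± 0.74) and Gfi1 (-1.30 ± 0.29) were not called at 8 h (adjusted p = 0.142 and 0.0605), but were with a replicate block (adjusted p = 0.00574 and 0.0318). At 24 h 8 genes differed, Tnfsf4 most (-3.04 ± 0.42 SE, adjusted p = 0.00185). At 72 h 2 did, Slc16a5 (2.23 ± 0.39 SE, adjusted p = 0.0312) and A430093F15Rik (-1.45 ± 0.25, adjusted p = 0.0312), a gene outside the naming rule that was chosen after its values were seen.

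These counts rested on few arrays. They were 16, 75, 14 and 3 at the 4 times with a replicate block and 13, 58, 11 and 2 without the in vitro array that stood apart. At 2 h the count was 2, 3 and 3 without Tconv 0 h number 1, Tconv 2 h number 1 and Treg 2 h number 2. At 8 h it was 13, 16, 15, 13, 10, 14 and 15 without Tconv 0 h number 1, Tconv 8 h number 1, Treg 0 h number 1, Tconv 0 h number 2, Tconv 8 h number 2, Treg 0 h number 2 and Treg 8 h number 2. At 24 h it was 2, 1, 1, 1, 1, 1 and 2 without Tconv 0 h number 1, Tconv 24 h number 1, Treg 0 h number 1, Treg 24 h number 1, Tconv 0 h number 2, Treg 0 h number 2 and Treg 24 h number 2. At 72 h limma gave 0 without each of the 8 arrays, against 119 genes at an unadjusted p under 0.05 with all of them. Il2 and Il2ra at both early times, Il21 at 8 h and Tnfsf4 at 24 h kept their calls without each array. The call of Il21 at 2 h was lost without Tconv number 1 at 0 or 2 h (-1.62 and -1.59), and that of Il23r without these or Treg 2 h number 2 (1.82, 1.66 and 1.81). Gfi1 at 2 h was not called without those Tconv arrays (-1.46 and -1.45) or any Treg array (-1.65 to -1.64) or after centring (-1.61). Socs2 was not called without any array but Tconv 2 h number 1 and Treg 0 h number 1 (1.73 to 2.01). At 8 h the call of Scin was lost without Tconv 8 h number 1 (2.29) and that of Id3 without Tconv 0 h number 1, Tconv 8 h number 2 or Treg 0 h number 2 (-2.02, -2.11 and -1.97). That of Id2 was lost without any array but Tconv number 1 at 0 and 8 h and Treg 8 h number 1 (2.39 to 2.54). Slc16a5 at 72 h lost its call without each array (2.14 to 2.33) and after both scalings (2.45 and 2.29). Of the genes called at 8 h 41.4% were higher in the Treg response, 62.2% after quantile normalization and 30.8% after centring. At 24 h these shares were 37.5%, 33.3% and 0%, of only 8, 3 and 1 called genes.

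Between cell types the responses went the same way for most genes called in both. Across all genes, which are not independent replicates, the Tconv and Treg changes in vivo correlated with r = 0.8 at 2 h, 0.83 at 8 h, 0.66 at 24 h and 0.4 at 72 h. At 2 h 309 genes were higher in both, against 19 expected of independent lists of those lengths, and 26 were lower in both, against 0.8. At 8 h 700 were higher and 303 lower in both, against 114.1 and 26.9, and 4 went opposite ways. The Treg change regressed on the Tconv change over the genes called in Tconv had a slope of 0.92 at 2 h, 0.64 at 8 h, 0.53 at 24 h and 0.31 at 72 h. Choosing genes by their Tconv change lowers such a slope by itself, so these values do not show a weaker answer in Treg.

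Rat IgG served as a control for the injection at 24 h, with n = 1 array per cell type, whose spread was taken to be that of the other groups. After KT3, levels above those on that array were found for Lag3 (4.25 ± 0.40 SE, adjusted p = 1.24e-06), H2ac4 (3.65 ± 0.41), Tnfsf4 (3.33 ± 0.37) and the mitotic kinase Bub1 (3.15 ± 0.47) in Tconv. Slc16a5 (-2.41 ± 0.34) and Ggt5 (-1.33 ± 0.25) were lower. Among cell cycle genes in Tconv, 18 of 21 rose and 3 were not called (20 adjusted over the list alone, list test adjusted p = 0.000145). In Treg Gzmb (2.34 ± 0.41), Ccr8 (2.18 ± 0.42) and Eomes (2.14 ± 0.37) were higher, and among the cell cycle genes 1 of 21 rose and 20 were not called (20 adjusted over the list alone, list test adjusted p = 0.00775, adjusted p = 0.177 with an estimated correlation), 8 rising with a replicate block. The counts were 183 in Tconv, 86 and 187 without the KT3 array number 1 or 2. They were 34 in Treg, 1 and 157 without number 1 or 2, 90 with a replicate block and 120 without the in vitro array that stood apart. The calls of Ccr8 and Eomes were lost without the KT3 array number 1 (1.90 and 2.32), and those of Gzmb, Ccr8 and Eomes with the number of sorts as a covariate (2.40, 1.98 and 2.27). Both Treg KT3 arrays at 24 h were single sorted and the Treg IgG array double sorted. The number of sorts thus goes with the treatment in that comparison and cannot be told apart from it. The KT3 mean also includes an array numbered 1, which held more RNA of other-cell markers, while both IgG arrays carry number 2. In Treg centring moved the median of all genes from 0.10 to 0.25 and quantile normalization moved it to -0.05. Rat IgG against 0 h gave 0 genes in both cell types with limma, and 19 and 198 at an unadjusted p under 0.05.

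In culture no unstimulated sample was used here, so changes from 0 h hold the effect of culture as well as that of KT3. In Tconv at 2 h Nr4a3 rose by 5.64 ± 0.42 (SE, adjusted p = 5.94e-10), Irf4 by 4.74 ± 0.27, Nr4a1 by 4.70 ± 0.36 and Egr2, a transcription factor induced by calcium signalling, by 4.51 ± 0.31. Without the 0 h array that stood apart these were 5.15 ± 0.48, 4.64 ± 0.32, 4.20 ± 0.41 and 4.14 ± 0.37, all called. Dtx1, a regulator of Notch signalling, fell by 2.004. Of the early receptor response genes, 15 of 17 rose, 1 fell and 1 was not called (15 up and 1 down adjusted over the list alone, list test adjusted p = 6.16e-08, adjusted p = 0.0809 with an estimated correlation), and 11 rose without that array. Of the NF-kB and NFAT targets, 9 of 10 rose and 1 was not called (9 up and 1 down adjusted over the list alone, list test adjusted p = 2.01e-09, adjusted p = 0.0625 with an estimated correlation), 1 falling with a replicate block, and 9 rose without that array. At 8 h Irf4 (4.74 ± 0.27), Tnfrsf9 (4.28 ± 0.27) and Il2ra (3.97 ± 0.31) rose. Igfbp4 (-3.04 ± 0.30) and the intermediate filament Vim (-2.67 ± 0.38) fell. Of the cholesterol synthesis genes, 9 of 9 rose (9 adjusted over the list alone, list test adjusted p = 1.01e-06, adjusted p = 0.0809 with an estimated correlation), and 9 rose without the array. Of the ribosome biogenesis genes, 14 of 14 rose (14 adjusted over the list alone, list test adjusted p = 1.35e-06, adjusted p = 0.081 with an estimated correlation), and 9 rose without it. At 24 h Lag3 (3.64 ± 0.33), Ms4a4c (3.61 ± 0.53) and Ifi27l2a (3.37 ± 0.33), and at 72 h Ms4a4c (4.06 ± 0.53), Eomes (3.19 ± 0.30) and Lag3 (3.16 ± 0.33), led the rises. The AP-1 gene Jun (-3.01 ± 0.52) and Dtx1 (-2.22 ± 0.28) were lowest at 72 h. Dendritic cell markers were called at 72 h (list test adjusted p = 0.0357), a call lost without the 0 h array that stood apart. With a replicate block the lists of CD8 T cell markers (adjusted p = 0.206 to 0.012) and dendritic cell markers (0.0514 to 0.045) were called at 2 h.

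The Tconv counts in culture were 3271 at 2 h (2426 were higher and 845 lower), 2350 at 8 h (1950 were higher and 400 lower), 3336 at 24 h (2406 were higher and 930 lower) and 938 at 72 h (826 were higher and 112 lower). Without the 0 h array that stood apart they were 619, 1276, 160 and 134, of which 462, 799, 134 and 107 were shared with the full counts. Without the 3 arrays of narrowest range they were 807, 665, 206 and 167, and with a replicate block 5174 at 2 h and 2787 at 72 h. Leaving out each array in turn gave 619, 899, 7431 and 1606 at 2 h, 1276, 1780, 6193 and 1335 at 8 h, 160, 493, 7726 and 1612 at 24 h and 134, 161, 6926 and 233 at 72 h. The share of called genes that were higher was 74.2%, 83%, 72.1% and 88.1% at the 4 times and 54.3%, 61.6%, 59.1% and 61.6% after quantile normalization. It was 91.6%, 92.2%, 88% and 93.9% after median centring and 55.6%, 45.8%, 72.5% and 67.9% without that array. Median centring moved the median change of all genes from 0.06 to 0.25, from 0.02 to 0.15, from 0.23 to 0.43 and from 0.15 to 0.30.

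In Treg in culture, interferon-stimulated genes rose by 8 h and cell cycle genes by 72 h. At 2 h the peptide receptor partner Ramp3 (4.64 ± 0.30 SE, adjusted p = 2.11e-10), Nr4a3 (4.63 ± 0.42) and the zinc finger gene Plagl1 (3.65 ± 0.28) rose. Dtx1 (-2.004 ± 0.283) and the cytoskeletal Septin9 (-2.04 ± 0.30) fell. Of the early receptor response genes, 10 of 17 rose and 7 were not called (11 up and 1 down adjusted over the list alone, list test adjusted p = 5.52e-06, adjusted p = 0.0625 with an estimated correlation), 1 falling with a replicate block. At 8 h Cxcl10, a chemokine induced by interferon (4.60 ± 0.51 SE, adjusted p = 1.5e-06), Ifit3 (4.50 ± 0.63) and Ifit1 (4.18 ± 0.57) led the rises. Of the interferon-stimulated genes, 14 of 16 rose and 2 were not called (15 adjusted over the list alone, list test adjusted p = 3.26e-06, adjusted p = 0.0625 with an estimated correlation). Of the STAT5 and SOCS feedback genes, 6 of 8 rose and 2 were not called (6 adjusted over the list alone, list test adjusted p = 8.12e-06, adjusted p = 0.0721 with an estimated correlation). At 24 h Ifit3 (3.90 ± 0.63), Scin (3.81 ± 0.31) and Gzmb (3.56 ± 0.34) rose. The list of CD8 T cell markers was not called then (list test adjusted p = 0.281), but was with a replicate block (adjusted p = 0.0302). Of the interferon-stimulated genes, 8 of 16 rose and 8 were not called (12 adjusted over the list alone, list test adjusted p = 0.000589, adjusted p = 0.215 with an estimated correlation). At 72 h Scin (4.75 ± 0.31), Bub1 (4.21 ± 0.39), Il12rb2 (4.21 ± 0.49) and Kif11 (4.02 ± 0.33) rose. Of the cell cycle genes, 20 of 21 rose and 1 was not called (21 adjusted over the list alone, list test adjusted p = 6.26e-08, adjusted p = 0.0615 with an estimated correlation). The phosphatase Dusp1 (-2.69 ± 0.36), Dtx1 (-2.53 ± 0.28) and the orphan receptor Gpr83 (-2.31 ± 0.23) fell.

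The Treg counts in culture were 701 at 2 h (499 were higher and 202 lower), 697 at 8 h (561 were higher and 136 lower), 739 at 24 h (623 were higher and 116 lower) and 1132 at 72 h (912 were higher and 220 lower). With the shared spread estimated without the Tconv array that stood apart they were 1371, 1400, 1767 and 2033, which held all genes of the full counts, and with a replicate block 1250, 1400, 2040 and 2018. The 0 h array number 1 had a narrow range too, and without the 3 such arrays the counts were 651, 491, 494 and 1143, of which 470, 394, 374 and 825 were shared. Leaving out each array in turn gave 293, 373, 1003 and 393 at 2 h, 213, 188, 1527 and 488 at 8 h, 164, 199, 2207 and 274 at 24 h and 619, 487, 1514 and 869 at 72 h. Of the called genes 71.2%, 80.5%, 84.3% and 80.6% were higher at the 4 times, 52.7%, 54.8%, 52.4% and 59.4% after quantile normalization. The share was 87.7%, 89.3%, 94.5% and 87.2% after median centring, which moved the median of all genes from -0.02 to 0.10, from 0.07 to 0.18, from 0.07 to 0.22 and from 0.05 to 0.15.

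**Figure D4:**
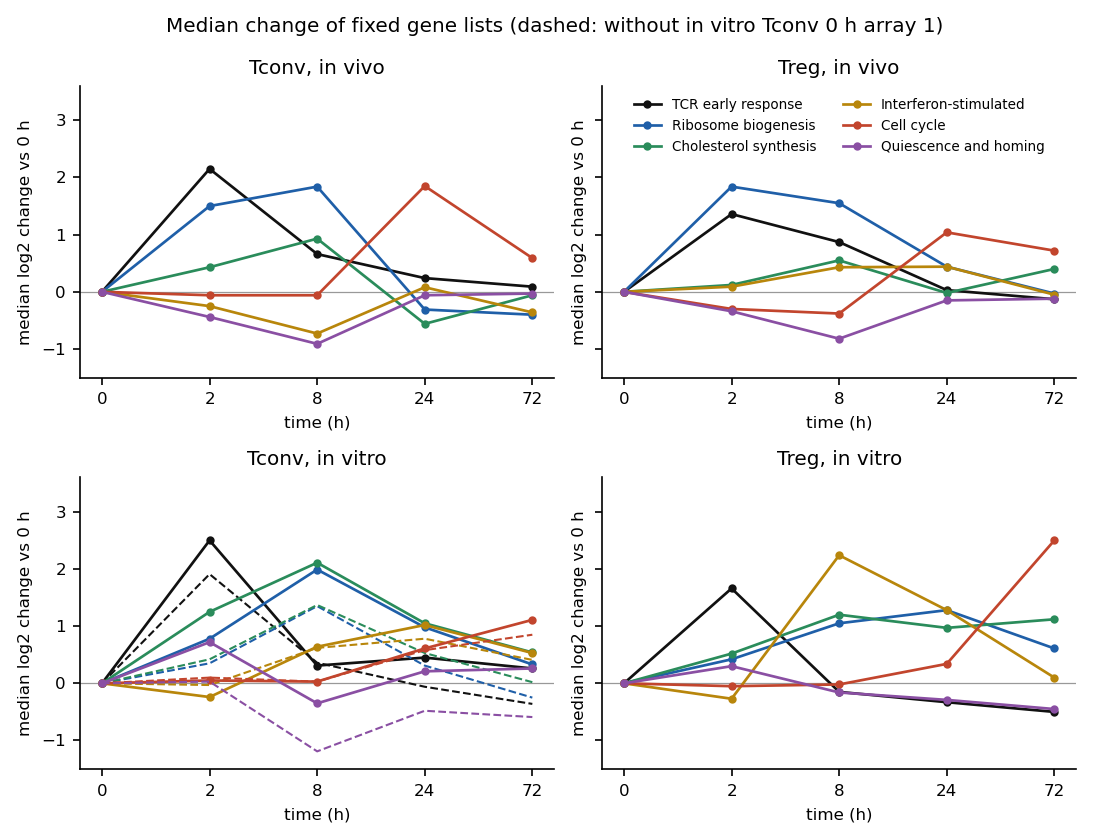
Median log2 change from 0 h of 6 gene lists by time after KT3, in 4 panels for cell type and setting, with dashed lines for in vitro Tconv without the 0 h array number 1. The cell cycle median peaks at 24 h in Tconv in vivo and at 72 h in Treg in vitro.

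In culture the response differed between the cell types for 18, 81, 61 and 222 genes at 2, 8, 24 and 72 h. Plagl1 rose more in Treg at 2 h (3.54 ± 0.39 SE, adjusted p = 2.93e-05), as did Lrrc32, the latency receptor GARP (2.99 ± 0.41), and Scin at 24 h (3.75 ± 0.43) and 72 h (4.72 ± 0.43). At 72 h the mitotic genes Bub1 (3.50 ± 0.55) and Ncapg (3.23 ± 0.51) rose more in Treg. Of the cell cycle genes, 5 of 21 rose and 16 were not called (15 adjusted over the list alone, list test adjusted p = 0.0424, adjusted p = 0.136 with an estimated correlation) in Treg relative to Tconv, and 14 rose with a replicate block. At 8 h the list of interferon-stimulated genes had an adjusted p of 0.0955, 0.00745 with the block. Rgs16 at 8 h (-2.53 ± 0.36), Lag3 at 24 h (-3.39 ± 0.46) and the chemokine receptor Cxcr5 (-3.12 ± 0.48) and Neurl3 (-3.14 ± 0.33) at 72 h were lower in the Treg response. The counts without the 0 h Tconv array that stood apart were 13, 225, 54 and 189, of which 7, 61, 32 and 132 were shared. They were 8, 24, 27 and 90 without the 3 arrays of narrowest range and 36, 480, 297 and 439 with the block. They were 3839, 2550, 3406 and 3079 without Tconv 0 h number 2. At 2 h the count was also 4, 10, 9, 5 and 7 without Tconv 2 h number 1 or 2, Treg 0 h number 1, or Treg 2 h number 1 or 2. At 8 h it was 15, 17, 39 and 44 without Tconv 8 h number 1, Treg 0 h number 1, or Treg 8 h number 1 or 2. At 24 h it was 19, 35, 37 and 22 without Tconv 24 h number 1, Treg 0 h number 1, or Treg 24 h number 1 or 2, and at 72 h 108 and 105 without Tconv or Treg 72 h number 1. The share higher in Treg at the 4 times was 72.2%, 63%, 41% and 70.7%. It was 57.1%, 47.6%, 22.6% and 49.5% after quantile normalization, 62.5%, 68.4%, 43.6% and 75.7% after centring, and 92.3%, 92%, 68.5% and 87.8% without the array that stood apart.

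The responses in vivo and in culture were compared within each cell type by an F-test over the 4 times. It called 791 genes in Tconv and 1349 in Treg. In Tconv Il21 rose at 8 h in vivo by 5.46 ± 0.28 (SE, adjusted p = 1.46e-12) more than in culture, and Gzmb by 3.45 ± 0.48 more. Adh1 (-3.60 ± 0.46) and the interferon-stimulated gene Rtp4 (-3.77 ± 0.57) were lower in vivo, as was Vps37b, an endosomal sorting gene, at 2 h (-3.60 ± 0.39). Of the cytokines and chemokines at 8 h, 3 of 17 rose and 14 were not called (4 adjusted over the list alone, list test adjusted p = 0.000198) in vivo relative to culture. In Treg Ramp3 (-4.64 ± 0.43) and the transcriptional repressor Bcl6 (-3.61 ± 0.44) were lower in vivo at 2 h, Tgm2 was higher at 8 h (4.002 ± 0.571), and Scin was lower at 72 h (-4.25 ± 0.43). Of the interferon-stimulated genes at 8 h in Treg, 6 of 16 fell and 10 were not called (14 adjusted over the list alone, list test adjusted p = 0.00636, adjusted p = 0.122 with an estimated correlation). Of the cell cycle genes at 72 h, 11 of 21 fell and 10 were not called (19 adjusted over the list alone, list test adjusted p = 0.00251, adjusted p = 0.0754 with an estimated correlation). The Tconv count was 491, 485 and 5240 without the 2 h array number 1 in vivo, the 2 h array number 1 in vitro or the 0 h array number 2 in vitro. The Treg count was 2264 without the Tconv array that stood apart. Without the 3 arrays of narrowest range the counts were 1293 and 2433, and with a replicate block 1710 and 2296. Across all genes, which are not independent replicates, the changes in the 2 settings correlated in Treg with r = 0.3, 0.44, 0.46 and 0.51 at 2, 8, 24 and 72 h, and in Tconv with r = 0.25, 0.73, 0.44 and 0.21. Without the array that stood apart the Tconv values were 0.41, 0.71, 0.48 and 0.42. At 2 h in Treg 98 genes were higher in both settings, against 25.1 expected of independent lists, and 18 went opposite ways, while without that array these were 189, against 68.8, and 50. At 8 h in Treg 221 were higher in both, against 35.7, and 2 went opposite ways, while without it these were 477, against 107.9, and 11. At 8 h in Tconv 1186 were higher in both, against 281.6, and 9 went opposite ways, while without the array these were 541, against 110.5, and 4.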

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

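The tests of even compression, of age and sex, of single sorting, of normalization and of unequal start levels were chosen only after the result was seen; the others were chosen before, that of RNA of other cells as the source of the markers with the markers already seen but not the genes it uses.

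The in vitro Tconv 0 h array number 1 stood apart from array number 2 of its group, and its deviation was shared by number 1 of Tconv at 8 h (0.71) and Treg at 0 h (0.65), which had the next narrowest interquartile ranges (2.097 and 2.192). Age and sex of the mice, which go with the array number in culture, are argued against as the whole source: the difference between numbers 1 and 2 at 0 h correlated across genes with that at the other 4 in vitro Tconv times by a median of 0.09 (-0.13 to 0.71), although a part of it may remain. Even compression of the signal, which would keep the order of the genes, is argued against as the whole source as well, with a rank correlation with number 2 of 0.553 against 0.876 to 0.981 in the other 19 groups, while added noise, and what these 3 arrays have in common, stay open as untested. RNA of another cell type stays open but rests on little: of 9 marker lists, 1 exceeded its brightness-matched genes by over 0.5, that of dendritic cells (0.6, 3 genes), with neutrophils at 0.37 and B cells at 0.34. Zbtb46, Siglech and Flt3 stood at 7.34, 7.33 and 7.15 on that array and at 6.43, 6.57 and 6.04 on number 2.

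Markers of other cell types, namely B cells, macrophages, neutrophils and platelets, were higher on the in vivo number 1 arrays in 10 of 10 pairs, as were those of CD8 T cells, while those of erythroid and plasma cells were in 9 and those of dendritic and NK cells in 8 and 6. Single sorting of the number 1 samples is argued against if the sort labels hold, because the markers differed by 1.08 in Tconv at 8 h, where number 1 was double and number 2 single sorted, and by 1.00 in Treg at 24 h, where both were single sorted, but these are the 2 pairs whose labels break the order of the other 8. A shift of dim genes is argued against as well, since brightness-matched genes differed by 0.28 against 1.24 for the markers. RNA of other cells in the number 1 samples may be the source: of 11 tested genes of B cells and myeloid cells outside these lists, 10 (90.9%) were higher in number 1 in at least 9 of 10 pairs, against 16.2% of all genes, by a mean of 1.72. The sort for CD4 would remove such cells, no biological explanation was tested, and differences between mice stay open as untested.

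The response of Treg and Tconv differed at 8 h in vivo for 29 genes. Normalization of the deposited values is argued against as the source of these 29 differences alone, since 28 of them kept their direction and at least 80% of their size after quantile normalization. They were picked for large differences in the same values, which favours this outcome. Which genes were called did depend on scaling: 41.4% were higher in the Treg response, 62.2% after quantile normalization and 30.8% after median centring. RNA of other cells in the number 1 samples is argued against as the whole source too, since the number 2 arrays alone gave 29 in the same direction, with a median size of 104.3% of the full one. The number 2 arrays were also part of the data that picked these genes, so this agreement is in part built in. Unequal start levels that meet at 8 h stay open, with 16 of the 29 genes, Il2ra among them, differing less between the cell types at 8 h than at 0 h. Of these 10 had crossed over, while 13 genes, Il2 and Il21 among them, differed more at 8 h. That the cell types answer KT3 differently at these genes is therefore a hypothesis from the same data, with 10 to 21 genes called when single arrays were left out.

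The test of the difference between the Treg and Tconv responses marked 6, 29, 8 and 2 genes at 2, 8, 24 and 72 h in vivo and 18, 81, 61 and 222 in culture, and the F-test between settings marked 791 in Tconv and 1349 in Treg. Those with the largest differences in either direction, and called regulators, are named here. In vivo at 2 h they were Socs2 (1.95, Treg minus Tconv change), Il23r (1.87), Gfi1 (-1.64), Il21 (-1.79), Il2ra (-2.96) and Il2 (-2.99). At 8 h they were Scin (2.55), Id2 (2.53), Slc16a5 (1.94), Id3 (-2.19), Il2 (-3.05), Il2ra (-3.11) and Il21 (-3.29). At 24 h they were Slc16a5 (2.12), Rrs1 (1.68), Bmyc (1.13), Ctla4 (-2.24), H2ac4 (-2.44) and Tnfsf4 (-3.04), and at 72 h Slc16a5 (2.23). In vivo the members of the gene lists called beyond these were Lag3 (-2.48), Irf4 (-1.96) and Tigit (-1.98) at 8 h and Gpr83 (-1.70) and Izumo1r (-1.73) at 24 h. Leaving out single arrays of the 8 in each test ended many of these calls. At 2 h it did so for Socs2 with 6 of them (values of 1.73 to 2.01), Il23r with 3 (1.66 to 1.82), Gfi1 with 6 (-1.65 to -1.45) and Il21 with 2 (-1.62 and -1.59). At 8 h it did so for Scin with 1 (2.29), Id2 with 5 (2.39 to 2.54), Slc16a5 with 7 (1.80 to 2.04) and Id3 with 3 (-2.11 to -1.97), as well as Lag3 with 6 (-2.58 to -2.24), Irf4 with 6 (-2.04 to -1.76) and Tigit with 8 (-2.17 to -1.79). At 24 h it did so for Slc16a5 with 8 (1.97 to 2.28), Rrs1 with 7 (1.43 to 1.84), Bmyc with 8 (1.05 to 1.20), Ctla4 with 6 (-2.31 to -1.80), H2ac4 with 7 (-2.74 to -2.04), Gpr83 with 7 (-1.80 to -1.34) and Izumo1r with 7 (-1.78 to -1.51), and at 72 h for Slc16a5 with 8 (2.14 to 2.33). All 7 of these genes at 24 h also lost their calls after median centring and with no filter on dim clusters, while Tnfsf4 kept its call.

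In culture the largest differences, with called regulators, were those of Plagl1 (3.54), Lrrc32 (2.99), Slc16a3 (2.34), Egr2 (-2.20), Irf4 (-2.21) and Tnf (-2.25) at 2 h. At 8 h they were those of Cxcl10 (3.48), Plagl1 (3.28), Il12rb2 (3.11), Il2ra (-2.42), Rgs16 (-2.53) and Itm2a (-2.95). At 24 h Scin (3.75), Gzmb (3.27), Plagl1 (2.79), Ephx1 (-2.50), Cd7 (-2.52) and Lag3 (-3.39) led. At 72 h the genes were Scin (4.72), Bub1 (3.50), Ncapg (3.23), Gfi1 (-1.23), Id3 (-1.47), Cxcr5 (-3.12), Neurl3 (-3.14) and Ms4a4c (-3.35). Further called list members are not named here. Leaving out single arrays ended the call of Slc16a3 with 6 of 8 (1.86 to 2.47), Egr2 with 6 (-2.39 to -1.83), Irf4 with 3 (-2.17 to -1.79) and Tnf with 6 (-2.44 to -1.71) at 2 h. It ended that of Cxcl10 with 4 (2.97 to 3.55), Il12rb2 with 4 (2.40 to 3.17) and Il2ra with 1 (-2.17) at 8 h, and of Gfi1 with 4 (-1.28 to -1.11), Id3 with 7 (-1.66 to -1.18) and Ms4a4c with 4 (-3.01 to -2.51) at 72 h. Each of these culture values rests in part on the Tconv 0 h array that stood apart.

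A signal also lay outside the measurement of named genes. Of 2341 transcript clusters above the filter that carried no name or several, 412 were called in Tconv at 8 h in vivo (302 higher and 110 lower) and 240 in Treg (170 higher and 70 lower).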

How the results depend on the processing

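The fits without the in vitro Tconv array that stood apart, without the 3 in vitro arrays of narrowest range and with a replicate block for each cell type and setting were chosen only after the data were seen; the others were planned. Of the counts of called genes, those within 1.5 times the full count were 30 of 32 with every transcript cluster, 30 of 32 with no filter, 25 of 32 after median centring, 23 of 32 after quantile normalization, 23 of 32 with the planned replicate block, 8 of 32 with the finer block, 9 of 30 within 1 setting, 6 of 17 with the sort covariate, 9 of 22 without the array that stood apart, 4 of 15 without the 3 arrays of narrowest range and 73 of 184 after leaving out 1 array. Of the values of named genes, with no filter 82 of 1295 lost their call, with centring 93 lost and 1 gained it, with quantile normalization 113 lost and 9 gained it, within 1 setting 195 of 1110 lost and 8 gained it, with the sort covariate 24 of 473 lost and 7 gained it, and without the array that stood apart 8 of 797 gained it. After leaving out 1 array 1734 of 8492 lost and 30 gained it. A called value went against the direction in the full fit in 1 case: Id2 in Tconv in vitro at 8 h was not called (-0.07), rose by 0.82 without the 0 h array number 2 and fell by 0.95 without number 1. Of 197 list calls 5 had a median that changed sign under a scaling. Without the array that stood apart 32 list calls were gained and 28 lost. Dim signal over background set the limit for the 7327 genes removed by the filter, and a gene not called near the array median was not shown to be unchanged. The cause of the moved counts was not tested. Leaving out an array leaves fewer samples, unbalanced in array number. No filter or every cluster alters the number of genes tested.

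With the replicate block within each setting, the count was 126 and 22 for Treg in vivo at 24 and 72 h, 1689 for Tconv in vitro at 72 h, and 1131 for Treg in vitro at 24 h. It was 208, 108 and 341 for the response difference in vitro at 8, 24 and 72 h, 2781 for Treg against Tconv at 0 h in vitro, and 53 for KT3 against IgG in Treg. With the finer replicate block it was 767, 452 and 64 for Tconv in vivo at 2, 24 and 72 h, 1820, 200 and 53 for Treg in vivo at 8, 24 and 72 h, and 16, 75 and 14 for the response difference in vivo at 2, 8 and 24 h. It was 5174 and 2787 for Tconv in vitro at 2 and 72 h, 1250, 1400, 2040 and 2018 for Treg in vitro at 2, 8, 24 and 72 h, and 36, 480, 297 and 439 for the response difference in vitro at 2, 8, 24 and 72 h. It was 630 for Treg against Tconv at 0 h in vivo, 4398 for Treg against Tconv at 0 h in vitro, and 90 for KT3 against IgG in Treg. It was 1710 for the Tconv F-test, and 2296 for the Treg F-test. Of the gene values 2 lost and 9 gained a call with the planned block, and 1 lost and 14 gained it with the finer one. The finer block added 28 list calls and ended 3, activation receptors in Tconv at 24 h (adjusted p = 0.041 to 0.052) and, in Treg in vivo, cytokines at 8 h (0.0246 to 0.0574) and NF-kB targets at 24 h (0.0316 to 0.0557). The finer replicate block changed no other call of these genes and lists, and it was not run on the lists for in vivo minus in vitro. Between the cell types the deviations of arrays correlated by -0.17 to 0.32 in vivo (12 of 25) and -0.45 to 0.71 in vitro (16 of 25).

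Fitted within 1 setting, the count was 1067 and 55 for Tconv in vivo at 2 and 72 h, 1410, 1947, 27 and 1 for Treg in vivo at 2, 8, 24 and 72 h, and 14, 59 and 1 for the response difference in vivo at 2, 8 and 72 h. It was 960, 1294, 629 and 197 for Tconv in vitro at 2, 8, 24 and 72 h, 328, 301, 284 and 703 for Treg in vitro at 2, 8, 24 and 72 h, and 3, 21 and 4 for the response difference in vitro at 2, 8 and 24 h. It was 235 for Treg against Tconv at 0 h in vitro. With the number of sorts as a covariate it was 1183 and 64 for Tconv in vivo at 2 and 72 h, 1542, 2144, 26 and 0 for Treg in vivo at 2, 8, 24 and 72 h, and 13, 73 and 1 for the response difference in vivo at 2, 8 and 72 h. It was 612 for Treg against Tconv at 0 h in vivo, and 0 for KT3 against IgG in Treg. Without the in vitro array that stood apart it was 913 and 57 for Tconv in vivo at 2 and 72 h, 1319, 1869 and 101 for Treg in vivo at 2, 8 and 24 h, and 13 and 58 for the response difference in vivo at 2 and 8 h. It was 1371, 1400, 1767 and 2033 for Treg in vitro at 2, 8, 24 and 72 h, 120 for KT3 against IgG in Treg, and 2264 for the Treg F-test. Without the 3 arrays of narrowest range, number 1 of Tconv at 0 and 8 h and of Treg at 0 h, the count was 807, 665, 206 and 167 for Tconv in vitro at 2, 8, 24 and 72 h, 8, 24, 27 and 90 for the response difference in vitro at these times, and 301 for Treg against Tconv at 0 h in vitro. It was 1293 for the Tconv F-test and 2433 for the Treg F-test. Quantile normalization gave 32 and 1 for Treg in vivo at 24 and 72 h, 45, 3 and 1 for the response difference in vivo at 8, 24 and 72 h, and 2632 for Tconv in vitro at 72 h. It was 170 and 137 for the response difference in vitro at 8 and 24 h, and 3611 for Treg against Tconv at 0 h in vitro. Median centring gave 1 for Treg in vivo at 72 h, 1 and 0 for the response difference in vivo at 24 and 72 h, and 8, 38 and 39 for the response difference in vitro at 2, 8 and 24 h. It was 56 for KT3 against IgG in Treg. With no filter it was 1 for Treg in vivo at 72 h, and 1 for the response difference in vivo at 24 h. Testing every transcript cluster gave 5 for Treg in vivo at 72 h, and 1 for the response difference in vivo at 24 h. The counts of 0 came from limma, against 119 genes at an unadjusted p under 0.05 for the response difference at 72 h, 276 for Treg at 72 h and 1693 for KT3 against IgG in Treg in the fit to all arrays.

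Leaving out each array in turn, with the times in order, gave 133 to 463, 1511 to 1817, 137 to 260 and 10 to 22 for Tconv in vivo and 245 to 628, 425 to 683, 2 to 144 and 0 to 20 for Treg in vivo. It gave 2 to 9, 10 to 21, 1 to 9 and 0 for the response difference in vivo, where limma called 0 at 72 h without each of the 8 arrays. It gave 619 to 7431, 1276 to 6193, 160 to 7726 and 134 to 6926 for Tconv in vitro, and 293 to 1003, 188 to 1527, 164 to 2207 and 487 to 1514 for Treg in vitro. For single arrays the range was 4 to 3839, 15 to 2550, 19 to 3406 and 105 to 3079 for the response difference in vitro. It was 155 to 283 for Treg against Tconv at 0 h in vivo, 133 to 7570 for Treg against Tconv at 0 h in vitro, 86 to 187 for KT3 against IgG in Tconv and 1 to 157 for KT3 against IgG in Treg. It was 485 to 5240 for the Tconv F-test and 943 to 1566 for the Treg F-test.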

Other observations

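The lists in this part were fixed before the data were examined, but they were picked for description only after the result was seen. Among regulators of helper lineages in Tconv at 2 h in vivo 4 of 10 members rose and 6 were not called (5 adjusted over the list alone, list test adjusted p = 4.26e-05), with Tbx21 at 2.96 ± 0.33 and Batf, an AP-1 partner of Irf4, at 1.74 ± 0.29. In Treg at 2 h 6 of 10 members rose and 4 were not called (6 up and 1 down adjusted over the list alone, list test adjusted p = 5.77e-05, adjusted p = 0.0783 with an estimated correlation), with Eomes at 2.15 ± 0.30 and Batf at 1.82 ± 0.29, and with a replicate block 1 fell. At 8 h in Tconv 4 of 10 rose and 6 were not called (7 up and 1 down adjusted over the list alone, list test adjusted p = 0.00037, adjusted p = 0.331 with an estimated correlation), and with the block 6 rose and 1 fell. At 8 h in Treg 5 of 10 rose and 5 were not called (7 up and 1 down adjusted over the list alone, list test adjusted p = 0.000333, adjusted p = 0.144 with an estimated correlation). The difference between the cell types in this list was not called at 2 or 8 h (adjusted p = 0.981 and 0.981). Among cell death genes in Tconv at 2 h 4 of 8 rose and 4 were not called (4 adjusted over the list alone, list test adjusted p = 0.000486, adjusted p = 0.0514 with an estimated correlation), with Bcl2l11, which encodes the death protein Bim, at 1.84 ± 0.24 and Fasl at 1.71 ± 0.29. The list test in Treg at 2 h gave an adjusted p of 0.232 and that of the difference between the cell types 0.282.

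Of the cytotoxic genes at 72 h in vivo 1 of 6 rose and 5 were not called (3 up and 1 down adjusted over the list alone, list test adjusted p = 0.0111) in Tconv. In Treg 1 of 6 rose and 5 were not called (1 adjusted over the list alone, list test adjusted p = 0.0171), and 2 rose with a replicate block. The mean of NK cell markers went from 4.89 at 0 h to 5.00 at 72 h on number 1 and from 4.77 to 5.08 on number 2 in Tconv, and from 4.69 to 5.48 and from 4.59 to 4.66 in Treg. Only Eomes among these markers passed the dim filter, and it is also a regulator of T cells, so this mean cannot show NK cell RNA. Gzmb was the member that rose in both. In Tconv it was higher by 2.47 ± 0.34, 2.97 ± 0.34, 2.30 ± 0.34 and 2.24 ± 0.34 at 2, 8, 24 and 72 h, while the pore-forming protein Prf1 fell by 1.56 ± 0.27 at 8 h. In Treg at 2 h Gzmb rose by 1.39 ± 0.34, a call lost without either 0 h array (1.31 and 1.47) or the 2 h array number 1 (1.33).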
